A study of Mus musculus with 99 samples.

How the data were processed

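Polyadenylated RNA was measured by sequencing in 3 tissues of wild-type male C57BL/6 mice: gastrocnemius, quadriceps and whole spinal cord. Per the labels, tissues came from perfused mice, were frozen, extracted with Trizol and made into libraries with the TruSeq RNA v2 kit. The labels name 99 samples in 3 groups: sedentary at 10 months, sedentary at 18 months and exercised at 18 months. They do not state what the exercise consisted of. Each title carries a number such as 6.3, and the same number occurs in different tissues. The labels do not say that it marks the animal, nor what its first part means. Numbers starting with 1 to 3 occur only at 10 months and those starting with 4 to 10 only at 18 months, so any litter or cage behind them cannot be told apart from age.

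Reads were aligned with STAR 2.5.2b to GRCm38.p5, per the submitters' processing notes. The program that assigned reads to genes, and whether it used strand, are not given in the sources used here. The deposited tables hold whole-number counts per Entrez gene, not normalized, together with gene lengths and symbols. The deposited FPKM and TPM tables were recomputed exactly from the count table and its gene lengths. Every table held the same genes and columns for 97 libraries. The 2 remaining labelled samples, quadriceps 10.4 (18 months, sedentary) and 10.2 (18 months, exercised), were not analysed here. Groups therefore held 10, 10 and 13 libraries in gastrocnemius and cord, and 10, 9 and 12 in quadriceps. The design as first written counted 33 quadriceps libraries, 66 muscle libraries and 99 in all, where 31, 64 and 97 were fitted.

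Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, 1 tissue at a time. Each fit held all 3 groups of a tissue, with TMM factors and the genes kept by filterByExpr (minimum count 10, minimum total count 15). The 3 contrasts were 18 against 10 months in sedentary mice (ageing), exercised against sedentary at 18 months (exercise), and exercised 18-month against sedentary 10-month mice. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Fold changes are log2 values with standard errors (SE) taken from the F statistic, and expression is given as TMM-scaled CPM with the standard deviation (SD) between libraries. All p-values are two-sided, and adjusted p-values come from edgeR unless another tool is named.

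Differences between tissues were tested as contrasts of 1 edgeR fit over all libraries of the tissues concerned: the ageing and the exercise effect in gastrocnemius against quadriceps, the same effects in cord against the mean of both muscles, and gastrocnemius against quadriceps at 10 months. These fits had no term for the number shared between tissues.

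There were 44 gene lists, fixed with their members before the data were examined. Lists with at least 5 tested genes were tested with camera (limma 3.58.1, on voom values) at a preset correlation of 0.01, which compares a list with all other genes. The test was repeated with the correlation estimated from the data and with fry, which asks whether a list's genes move on balance one way. Adjusted p-values of lists run over the lists of a tissue and comparison. For each list, calls are also counted as adjusted over the list alone. List symbols were matched to the table's symbols and older names; 9 immunoglobulin constant genes and Trac, Trbc1 and Trbc2 were not matched.

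The genes named were set by a rule. It takes the 10 largest rises and falls per tissue and comparison among called genes with a mean log2 CPM of at least 1, leaving out predicted, pseudogene and small RNA symbols, or the 5 smallest p-values where none passed. It adds up to 4 called members of each list by p, 5 genes per direction between tissues, and 10 fixed muscle and 7 fixed cord genes. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined; those chosen later are named here and in the closing section.

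The ageing and exercise comparisons share the 18-month sedentary libraries. The share of ageing-changed genes with the opposite sign under exercise was therefore set beside 10 simulations of unchanged groups with the same libraries. In each simulation, as many genes were taken, by smallest ageing p, as were called in the real data. It was also set beside 10 random splits of the 18-month sedentary libraries, with one part used for ageing and the other for exercise. Library totals, mitochondrial share, the share of the 10 most abundant genes, and correlations of expression with gene length and GC content were compared between groups with permutation tests, exact for quadriceps and with random resamples otherwise, adjusted over 30 tests. The group tests of both correlations were chosen after the data were seen. GC content came from GENCODE M21 transcripts and covered 95.1%, 95.5% and 91.1% of tested genes in gastrocnemius, quadriceps and cord.

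Alternatives were DESeq2 1.42.0, RLE factors, no filter beyond a summed count of at least 1, a mean count of at least 50, only the 2 groups compared, voom with quality weights (limma), limma on log2 of the deposited TPM plus 1 or plus 0.1 (genes with mean TPM of at least 0.5), 2 surrogate variables (sva 3.50.0), an added fold change minimum of 0.5 on the log2 scale, and the first part of the number as a block. Alternatives chosen after seeing the data left out libraries that stand apart, added each library's slope on gene length as a covariate, or applied RLE factors to the lists. Each library was also left out in turn for ageing and exercise. Calls were recounted over 100 splits of the libraries per tissue and comparison, 60 for fits over both muscles and 40 for fits over 3 tissues, the real one included.

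Library totals ran from 29.06 to 62.77 M counts with a median of 38.71 M. The fits were tested on simulated data drawn from the real means, library sizes and dispersions, with 67 genes changed 1.3-fold, 67 changed 1.6-fold and 66 changed 2-fold. For ageing, the share of 1.3-fold changes recovered was 58.2% in gastrocnemius, 44.8% in quadriceps and 76.1% in cord, and that of 1.6-fold changes 91%, 92.5% and 97%. For exercise these were 68.7%, 61.2% and 80.6% at 1.3-fold and 89.6%, 94% and 98.5% at 1.6-fold. For an ageing difference between the muscles, 20.9% of 1.3-fold and 76.1% of 1.6-fold changes were recovered. Data simulated within each tissue without any change gave 0 calls. Changed genes were drawn only from those with a mean log2 CPM of at least 0. Simulated libraries carry no trend across genes, unlike some of the real ones. In the data with changed genes, 8 to 14 unchanged genes were called per tissue and comparison, and 2 for the difference between the muscles.

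Overlaps of exons were looked up in GENCODE M21: 30 of the 130 named genes share exon bases with a gene on the opposite strand. Without a statement on strand, reads of such genes cannot be told apart, and the longest overlaps are given beside the gene. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.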

Results

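Gene expression was measured in 97 RNA libraries from gastrocnemius, quadriceps and whole spinal cord of male C57BL/6 mice. The mice were sedentary at 10 months, sedentary at 18 months or exercised at 18 months, with 10, 10 and 13 libraries in gastrocnemius and in cord and 10, 9 and 12 in quadriceps. The comparisons ask what differs between sedentary mice of both ages, what exercise changes at 18 months, and whether leg muscle and cord differ in this. Total counts per library ran from 29.06 to 62.77 M, and medians per group lay between 37.32 and 40.49 M. Within each group no library was a copy of another, since the lowest chi-square per gene between libraries of a group was 3.23. Libraries are called by the number in their title.

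A few libraries stood apart from the rest of their tissue. In gastrocnemius and quadriceps, library 3.1 (10 months) had the largest deviation from the tissue mean, with a root mean square of 0.697 and 0.753 on the log2 scale. Gastrocnemius library 2.2 (10 months) had the lowest mitochondrial share, 7.15%, and a correlation across genes of -0.487 between its deviation and gene length. Cord library 5.2 (18 months, sedentary) had a correlation of 0.684 with GC content across genes and 1.58% mitochondrial counts. Cord library 6.1 (18 months, sedentary) had red cell transcripts, chiefly globins, at 11106 CPM and a correlation of -0.381 with gene length. Genes are not independent replicates in these correlations. Some exercised libraries deviated as well. Gas_10.2 and Gas_10.3 had correlations of -0.367 and -0.355 with gene length, and Quad_10.3 had the fewest genes detected in its tissue, 18665. The libraries left out below as standing apart are 3.1 and 2.2 in gastrocnemius, 3.1 in quadriceps and 5.2 and 6.1 in cord. All exercised libraries stayed in those fits. In 30 permutation tests of library measures between groups, of which those of gene length and GC content were chosen after the data were seen, 1 passed: the mitochondrial share in gastrocnemius was 12.4% ± 1.82 (SD, n = 13) in exercised and 10.5% ± 0.767 (SD, n = 10) in sedentary 18-month mice (p = 0.0013, adjusted p = 0.039). In cord it was 4.08% ± 0.898 at 18 and 4.61% ± 0.186 at 10 months (SD, n = 10 each; permutation p = 0.00718, adjusted p = 0.108).

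**Figure D1:**
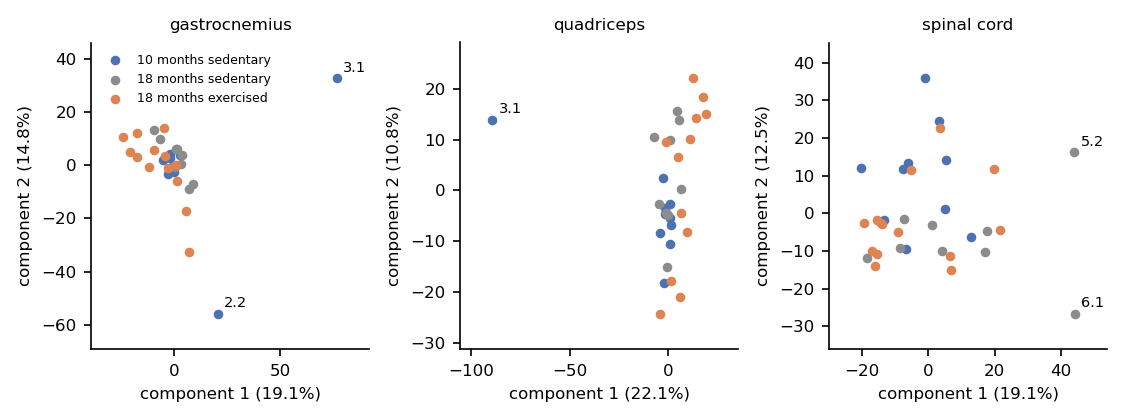
Principal components of log2 CPM in each tissue, with 1 point per library coloured by group and the share of variance on each axis. Libraries 3.1 and 2.2 in gastrocnemius, 3.1 in quadriceps and 5.2 and 6.1 in cord are labelled and lie away from most others.

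In sedentary spinal cord, 18-month mice had more transcript of genes of activated microglia than 10-month mice. The largest rises were in genes that microglia switch on around damaged myelin and neurons, such as Cst7, which encodes a cysteine protease inhibitor, and Gpnmb and Lgals3, which encode a membrane glycoprotein and a galectin. The astrocyte filament gene Gfap and the complement gene C4b lay above the 10-month median in all 10 libraries. Of 18956 genes tested, 535 were higher and 480 lower at 18 months, and 4987 had an unadjusted p under 0.05 where chance gives 948. With each library's slope on gene length as a covariate, a setting chosen after the data were seen, 575 were higher and 225 lower, with 365 of the 1015 calls among them, and with only both compared groups fitted 205 were higher and 47 lower. More were lower than higher with DESeq2 (790 up and 822 down) and with limma and quality weights (997 up and 1263 down). Of the called genes, 163 changed by at least 0.5 on the log2 scale, 150 of them up.

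Cst7 (Entrez 13011, chromosome 2, 150570415 to 150578944 in GRCm38) rose from 0.516 ± 0.228 to 2.41 ± 0.475 CPM (SD, n = 10 each), a log2 fold change of 2.24 ± 0.187 (SE, adjusted p = 8.17e-10). Gpnmb (Entrez 93695, chromosome 6, 49036546 to 49070929) rose from 3.45 ± 0.858 to 14.2 ± 4.82 CPM, by 2.05 ± 0.201 (adjusted p = 2.26e-08). Lgals3 rose by 1.65, Itgax, an integrin of dendritic cells and microglia, by 1.81, and Clec7a, a receptor for fungal glucans, by 1.28. Slc15a3, a lysosomal transporter, rose by 1.04 ± 0.0908 (adjusted p = 1.67e-09), but its exons share 1541 bases with Tmem132a on the opposite strand. Cd22 and Lilrb4a, both inhibitory immune receptors, rose by 1.03 and 1.09, and the lysozyme gene Lyz2 by 0.99; Lilrb4a shares most of its exon sequence with an overlapping gene model and is uncertain. C4b (Entrez 12268, chromosome 17, 34728380 to 34743882) rose from 137 ± 27.2 to 222 ± 26.6 CPM, by 0.70 ± 0.0824 (adjusted p = 8.13e-07). Gfap (Entrez 14580, chromosome 11, 102887336 to 102900912) rose from 1207 ± 98.6 to 1615 ± 138 CPM, by 0.42 ± 0.056 (adjusted p = 8.58e-06). All 10 libraries at 18 months lay above every 10-month library for Cst7, Gpnmb, Lgals3, Itgax, Slc15a3 and Gfap. The complement gene C1qa rose by 0.71 (adjusted p = 0.000177), and the myelin gene Mbp by 0.16 (adjusted p = 0.0287). Rsad2, an interferon-induced gene, passed at 1.04 (adjusted p = 0.0459) with 1 library at 40 CPM, and LOC101056014 at 1.34 (adjusted p = 0.0232) with 1 library at 1319 CPM.

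**Figure D2:**
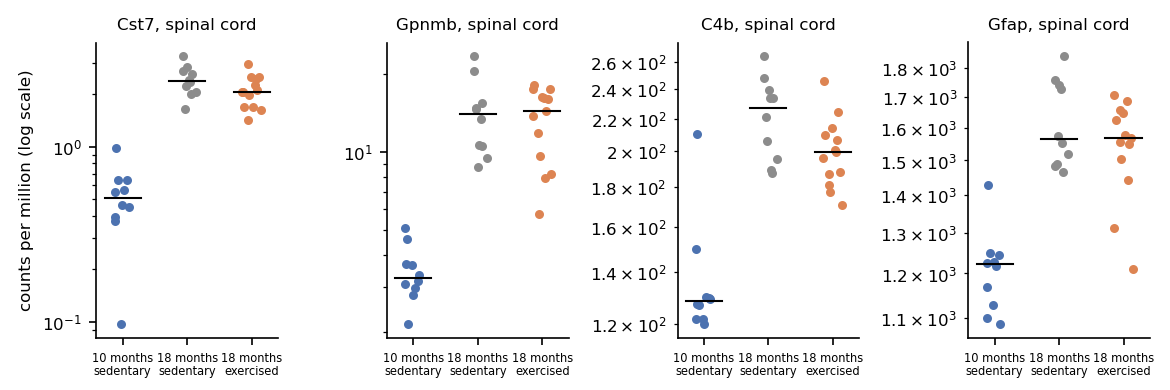
Expression in CPM (log axis) of Cst7, Gpnmb, C4b and Gfap in spinal cord, with 1 point per library, groups on the horizontal axis and bars at the medians. Both 18-month groups lie mostly above the 10-month group, though 10-month library 3.1, at 210 CPM for C4b, lies among the 18-month values. The exercised and sedentary 18-month groups overlap.

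The largest falls with age in cord were smaller than the rises. Myoc, which encodes the secreted protein myocilin, fell by 0.53 (adjusted p = 0.00736) and the long noncoding RNA Hotair by 0.53. Gpr17, a receptor of differentiating oligodendrocyte precursors, fell by 0.48 on the log2 scale (adjusted p = 0.00211). Rtl4 fell by 0.46, Acvr1c, a receptor for activin-like ligands, by 0.45, Banp by 0.41, the immediate early gene Nr4a3 by 0.41, Rxfp1 by 0.40, the synaptic adhesion gene Lrrtm2 by 0.40 and the apelin receptor gene Aplnr by 0.38. The motor neuron gene Chat (log2 fold change -0.14, adjusted p = 0.163) and the synaptic gene Snap25 (-0.12, adjusted p = 0.126) did not pass.

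Among the gene lists, 12 were called in cord with age. Disease-associated microglia genes were called up in 14 of 20 members over all genes and 18 adjusted over the list alone (adjusted p = 1.05e-22; 0.000766 with an estimated correlation). This was the only list whose call held with an estimated correlation. MHC class I presentation had 13 of 15 members up, among them H2-D1 (0.42) and H2-K1 (0.47), and 15 adjusted over the list alone (adjusted p = 4.83e-16; adjusted p = 0.083 with an estimated correlation). Interferon response had 9 of 29 up and 19 adjusted over the list alone, led by the chemokine gene Cxcl10 (1.397, adjusted p = 0.000634), with a list adjusted p of 3.24e-11 (adjusted p = 0.186 with an estimated correlation). Macrophage and microglia markers had 9 of 18 up, with Trem2, Cd68 and Tyrobp at 0.79, 0.89 and 0.68, and 12 up and 1 down adjusted over the list alone (adjusted p = 5.63e-11; adjusted p = 0.16 estimated). Reactive astrocyte genes had 7 of 20 up and 9 adjusted over the list alone, among them Serpina3n (0.28) and Timp1 (1.23), and complement had 6 of 17 up and 6 up and 1 down adjusted over the list alone (adjusted p = 3.46e-07 and 1.23e-06; adjusted p = 0.186 and 0.16 estimated). T and NK cell markers had 3 of 11 up, with Cd8a at 1.5997, and 7 adjusted over the list alone, and MHC class II presentation had 2 of 10 up and 3 adjusted over the list alone (adjusted p = 2.06e-05 and 5.43e-05; adjusted p = 0.16 and 0.186 estimated). Nuclear oxidative phosphorylation genes had 0 of 52 called and 47 fitted up, and cell cycle genes 1 of 18 called up (adjusted p = 9.14e-05 and 0.0459; adjusted p = 0.749 estimated for both). Mitochondrially encoded mRNAs had 1 of 13 called down and 3 adjusted over the list alone, and synaptic and neuronal genes, with Gad1 at -0.14 and Scn1a at -0.23, had 3 of 27 down and 5 adjusted over the list alone (adjusted p = 5.43e-05 and 0.00819; adjusted p = 0.459 and 0.186 estimated). With fry, 9 of the cord lists passed. Without cord libraries 5.2 and 6.1, nuclear oxidative phosphorylation and cell cycle genes lost their calls (oxidative phosphorylation, nuclear: adjusted p = 0.0663; cell cycle genes: adjusted p = 0.0881).

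Lists of cord cell types that were not called with age were astrocyte markers (median log2 fold change -0.05, adjusted p = 0.214), motor neuron genes (-0.03, adjusted p = 0.214), oligodendrocyte precursor genes (-0.07, adjusted p = 0.276), choroid plexus and ependymal genes (0.09, adjusted p = 0.453) and meningeal and dorsal root genes (0.03, adjusted p = 0.501). Oligodendrocyte and myelin genes moved both ways, with 2 up and 4 down, among the latter Mal and Ugt8a at -0.17 and -0.28 (list adjusted p = 0.329). Muscle genes in cord had a median of 0.04 (adjusted p = 0.151) and neutrophil and marrow markers one of 0.34 (adjusted p = 0.146). Red cell markers, a sign of blood in the tissue, had a median of 1.51 with 8 of 8 fitted up and 5 up adjusted over the list alone, and were not called (adjusted p = 0.214). Library 6.1 lay at 11106 CPM, while the other 9 sedentary 18-month libraries, at 199.6 to 1029 CPM, overlapped the 10-month libraries, at 277.0 to 1093 CPM. In the p53 targets and senescence list, Cdkn2a rose by 1.33 (adjusted p = 0.0084), while the list itself was not called (adjusted p = 0.939) and its median, -0.01, and mean, 0.08, differ in sign.

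The number of cord calls depended on single libraries. It was 454 (291 up and 163 down) without cord libraries 5.2 and 6.1, of which 393 were among the original calls. Leaving out 1 library at a time, it was 407 without 6.1, 422 without 6.4, 447 without 2.3, 468 without 1.1, 474 without 1.2, 485 without 2.2, 488 without 3.3, 565 without 1.4 and 657 without 6.2. It was 1698 without 2.1, 1858 without 7.4 and 1892 without SC_10.4. Cst7, Gpnmb, Itgax, Lgals3, Clec7a, C4b, Gfap, C1qa, Myoc, Hotair, Gpr17 and Acvr1c stayed called in every such fit, and Rsad2 lost its call in 17 of 33.

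In gastrocnemius, few genes differed between sedentary mice at 18 and 10 months. Those that did include a rise of Pfkfb3, which encodes a regulator of glycolysis, and Sh2d4a, an adaptor gene, and a fall of the imprinted gene Nnat. Of 15027 genes, 17 were higher and 6 lower, with 1479 at an unadjusted p under 0.05 where chance gives 751. With 2 surrogate variables 125 were higher and 100 lower, and with limma and quality weights 239 and 242.

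Sh2d4a (Entrez 72281, chromosome 8, 68276567 to 68347699) rose from 3.34 ± 0.465 to 5.498 ± 1.21 CPM (SD, n = 10 each), by 0.72 ± 0.108 (SE, adjusted p = 0.00136), with all 10 libraries above every 10-month library. Nnat (Entrez 18111, chromosome 2, 157560078 to 157562522) fell from 6.86 ± 3.54 to 2.43 ± 1.504 CPM, a log2 fold change of -1.49 ± 0.292 (adjusted p = 0.0233), below the 10-month median in 10 of 10 libraries. Pfkfb3 rose from 323 ± 89.6 to 576 ± 154 CPM, by 0.84 ± 0.181 (adjusted p = 0.0421). Fam174b rose by 1.77 and the collagen gene Col11a2 by 0.86 (adjusted p = 0.0233 each), the ceramidase gene Acer2 by 0.75 (adjusted p = 0.0233), Emb, which shares 686 exon bases with Gm17509, by 0.62, Tmem132b by 0.55, Tifa by 0.51 and Wbscr17 by 0.48. The amylase gene Amy1, which shares 1128 exon bases with Rnpc3, rose by 0.47 (adjusted p = 0.00538). Lbp fell by 0.41 (adjusted p = 0.049). Arc, an immediate early gene, rose by 1.21 (adjusted p = 0.0275), and Chrdl2, an inhibitor of bone morphogenetic proteins, fell by 1.02 on the log2 scale (adjusted p = 0.0168). The myosin genes Myh7, Myh2, Myh1 and Myh4 did not pass (adjusted p = 0.72, 0.937, 0.996 and 0.743), nor did Ppargc1a, Chrna1, Myog, Col1a1, Col3a1 or Cdkn1a (adjusted p = 0.992, 0.586, 0.798, 0.533, 0.498 and 0.932).

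With age in gastrocnemius 11 lists were called, and every call was lost with an estimated correlation (adjusted p = 0.134 for synaptic myonuclei and 0.736 for the other 10). Interferon response went up (adjusted p = 6.62e-09), with 0 of 29 members called over all genes and 9 adjusted over the list alone. MHC class I presentation (adjusted p = 0.00254), synaptic myonuclei (adjusted p = 0.00414), denervation response (adjusted p = 0.0197; 2 members adjusted over the list alone), red cell markers (adjusted p = 0.0262; 6 of 6 members adjusted over the list alone) and MHC class II presentation (adjusted p = 0.0384) also went up. Collagens and matrix went down (adjusted p = 0.00106; 4 members adjusted over the list alone), as did Schwann cell markers (adjusted p = 0.0186; 1 member), fatty acid oxidation (adjusted p = 0.0256) and adipocyte markers (adjusted p = 0.0384; 1 member). Heat shock proteins were called down (adjusted p = 0.0129) with a median of -0.09 but a mean of 0.01. In fry, synaptic myonuclei alone passed (adjusted p = 0.0432). For red cell transcripts, library 6.1 lay at 1284 CPM and the other 9 sedentary 18-month libraries between 51.4 and 93.9 CPM, where the 10-month libraries lay between 29.4 and 99.9. Without libraries 3.1 and 2.2, calls were lost for MHC class II presentation (adjusted p = 0.515), red cell markers (adjusted p = 0.0625), fatty acid oxidation (adjusted p = 0.557) and heat shock proteins (adjusted p = 0.557).

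Single libraries moved the gastrocnemius ageing count. It was 49 without libraries 3.1 and 2.2, with 16 of the original calls among them, and 80 without 3.1 alone. It was 3 without 1.2, 9 without 1.4, 10 without 6.1, 11 without 2.2, 13 without 1.1, 14 without 9.3, and 15 without 4.3 or without 8.2. Sh2d4a and Amy1 stayed called in every such fit.

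In quadriceps, ageing changed some of the same genes. Sh2d4a and Pfkfb3 rose and Nnat fell, and the leptin gene Lep, a fat cell hormone, also fell. Of 14790 genes, 36 were higher and 16 lower, with 1802 at an unadjusted p under 0.05 where chance gives 740.

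Quadriceps Sh2d4a rose from 3.53 ± 0.562 (n = 10) to 5.86 ± 1.097 CPM (SD, n = 9), by 0.74 ± 0.108 (SE, edgeR adjusted p = 0.00109), above the 10-month median in 9 of 9 libraries. Nnat fell from 6.71 ± 2.82 to 2.52 ± 1.05 CPM, with a log2 fold change of -1.43 ± 0.257 (adjusted p = 0.0062), and Lep from 4.69 ± 2.24 to 1.73 ± 0.657 CPM, with -1.44 ± 0.284 (adjusted p = 0.015). Among rises, the antibody joining chain gene Jchain went up by 1.59 (adjusted p = 0.0459), the fatty acid elongase gene Elovl6 by 1.49 (adjusted p = 0.0311) and Srrm4os by 1.14 (adjusted p = 0.0118). Pfkfb3 rose by 0.95, the adhesion gene Sdk1 by 0.90, the mitochondrial carbonic anhydrase gene Car5b by 0.90, Acer2 by 0.81, the growth factor gene Gdf11 by 0.66 and Tmem8 by 0.61. Among falls, Tmem100 had a log2 fold change of -0.84 and Tbc1d1, a regulator of glucose transport, one of -0.66 (adjusted p = 0.0482 and 0.0167). Arrdc3 fell by 0.62, the chaperone gene Dnajb4 by 0.42, the clock gene Cry1 by 0.41 and Rfesd by 0.31. Myh7, Myh2, Myh1 and Myh4 did not pass (adjusted p = 0.812, 0.923, 0.897 and 0.949), nor did Ppargc1a, Chrna1, Myog, Col1a1, Col3a1 or Cdkn1a (adjusted p = 0.878, 0.585, 0.394, 0.933, 0.891 and 0.984).

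Of the quadriceps lists, 8 were called with age, and each call was lost with an estimated correlation. Interferon response went up (adjusted p = 1.47e-07; adjusted p = 0.387 estimated), with 0 of 29 called over all genes and 5 up and 1 down adjusted over the list alone. MHC class I presentation went up and heat shock proteins down (adjusted p = 1.87e-06 each; adjusted p = 0.387 estimated for both), with 1 up and 3 down adjusted over the list alone. Adipocyte markers went up with 6 up and 1 down adjusted over the list alone, though the called member Lep fell (adjusted p = 0.00092; adjusted p = 0.485 estimated). Complement (adjusted p = 0.00858; 1 adjusted over the list alone; adjusted p = 0.804 estimated), synaptic myonuclei (adjusted p = 0.0168; 1; adjusted p = 0.387 estimated) and smooth muscle and pericyte markers (adjusted p = 0.0168; adjusted p = 0.535 estimated) went up, and fatty acid oxidation went down (adjusted p = 0.0361; adjusted p = 0.913 estimated). No list passed in fry, where the smallest adjusted p was 0.134. Without library 3.1, calls were lost for complement (adjusted p = 0.0518), smooth muscle and pericyte markers (adjusted p = 0.168) and fatty acid oxidation (adjusted p = 0.168). B and plasma cell markers, with Jchain, were not called (adjusted p = 0.135).

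Without library 3.1 the quadriceps ageing count was 113 and without 5.2 it was 109. It was 18 without 6.1, 20 without 9.3, 26 without 4.3, 28 without 2.2, 29 without 8.2, 31 without 3.3 and 32 without 2.1. It was 33 without 1.2 or without 1.4, and 34 without 1.1 or without 9.2. Sh2d4a, Srrm4os, Sdk1, Lep, Nnat and Tbc1d1 stayed called in every such fit.

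Both muscles shared 10 ageing calls of the same direction among 14656 genes tested in both, 6 up and 4 down. Among these were Acer2, Amy1, Erfe, Gm28651, Mlec, Mpzl3, Nnat, Pfkfb3 and Sh2d4a, and fold changes correlated across genes with r = 0.614. Muscle libraries of the same number tended to deviate together, with a median r of 0.28 over 31 pairs and -0.002 for other numbers. The shared calls and the correlation of fold changes are therefore not independent evidence from each muscle. The part of same-number libraries in this agreement was not tested. Gastrocnemius and cord shared 0 (r = 0.014), and quadriceps and cord shared 3, C130026I21Rik, Fastkd1 and Sugct (r = 0.095). No gene passed for a difference in the ageing effect between the muscles: edgeR and DESeq2 each called 0 of 15433, with 232 genes at an unadjusted p under 0.05 where chance gives 772. A count this far below chance means that p-values in this fit ran too large, so it is not evidence that both muscles age alike. The fit has no term for the number shared by libraries of both muscles, and its part in this was not tested. Small differences would be missed, as the edgeR fit recovered 20.9% of 1.3-fold differences on simulated counts, in which libraries are unrelated. The 5 smallest p-values there belonged to Meis2, Irs3, Arxes2, Acaa1b and Prkar2b (adjusted p = 1 each).

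Cord and muscle differed in their ageing effect. The microglial gene Gpnmb rose more in cord, and Nnat fell in both muscles but not in cord (0.20, adjusted p = 0.0809). Of 19735 genes, 213 had a higher and 303 a lower effect in cord than in the mean of both muscles, with 4027 at an unadjusted p under 0.05. The difference was 1.77 ± 0.259 (SE, log2) for Gpnmb (adjusted p = 8.05e-06) and 1.65 ± 0.255 for Nnat (adjusted p = 2.84e-05). It was 2.04 for Rnf182, 1.75 for Dscaml1 and 1.57 for the metallothionein gene Mt1 (adjusted p = 0.0477), whose sign turned to -0.09 without the libraries that stood apart. The difference was -1.59 for the peptide transporter gene Slc15a2, -1.35 for Fam174b, -1.35 for Stxbp5l, -1.14 for Arc (adjusted p = 0.0018) and -1.09 for Rspo2. Without the libraries that stood apart, 252 genes were called.

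**Figure D3:**
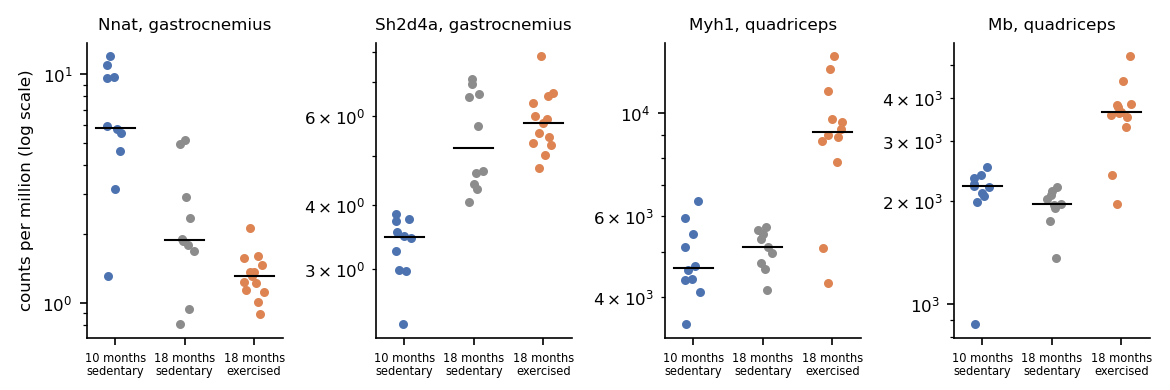
Expression in CPM (log axis) of Nnat and Sh2d4a in gastrocnemius and of Myh1 and Mb in quadriceps, with 1 point per library, groups on the horizontal axis and bars at the medians. Nnat is lower and Sh2d4a higher at 18 months, and Myh1 and Mb are higher in the exercised group.

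In gastrocnemius at 18 months, exercised mice had more transcript of the fast myosin Myh1 and of myoglobin (Mb) than sedentary mice. Of 15027 genes, 11 were higher and 5 lower, with 2051 at an unadjusted p under 0.05 where chance gives 751. With 2 surrogate variables 408 were higher and 416 lower, and with limma and quality weights 548 and 519.

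Myh1 (Entrez 17879, chromosome 11, 67200052 to 67224575) rose from 3151 ± 429 (n = 10) to 6565 ± 2507 CPM (SD, n = 13), by 1.06 ± 0.161 (SE, adjusted p = 0.00203), above the sedentary median in 13 of 13 libraries. Mb (Entrez 17189, chromosome 15, 77015487 to 77050670) rose from 1772 ± 136 to 3165 ± 1067 CPM, by 0.84 ± 0.162 (adjusted p = 0.026). The fatty acid elongase gene Elovl6, the citrate lyase gene Acly and the citrate carrier gene Slc25a1 rose by 1.93, 1.36 and 1.29 (adjusted p = 0.0391, 0.026 and 0.026), with a wide spread among exercised libraries: Acly lay at 49.7 ± 48.4 CPM. The carbonic anhydrase gene Car4 rose by 0.55, the chromatin gene Hmgb3 by 0.44 and the peroxisomal gene Phyh by 0.38. The Wnt receptor gene Fzd7 fell by 0.37 on the log2 scale (adjusted p = 0.0104), Prkab2, a subunit of the energy sensor AMPK, by 0.28, Wbp1l by 0.28, the myosin light chain kinase gene Mylk2 by 0.27 and Lgalsl by 0.25. Myh4, the fast glycolytic myosin, had a log2 fold change of -0.34 ± 0.0902 and did not pass (adjusted p = 0.0815), nor did Myh2 (0.50, adjusted p = 0.173), Myh7 (-0.15, adjusted p = 0.689) or Ppargc1a (-0.03, adjusted p = 0.931). Chrna1, Myog, Col1a1, Col3a1 and Cdkn1a did not pass either (adjusted p = 0.923, 0.852, 0.324, 0.368 and 0.622).

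Exercise moved 16 lists in gastrocnemius, and every call was lost with an estimated correlation. Nuclear oxidative phosphorylation was fitted up in 52 of 52 genes with a median of 0.17, with 0 members called over all genes or adjusted over the list alone (adjusted p = 2.2e-14; adjusted p = 0.552 estimated). Endothelial markers went up with 9 members adjusted over the list alone (adjusted p = 2.93e-08; adjusted p = 0.397 estimated; fry adjusted p = 0.0403). Collagens and matrix (adjusted p = 8.39e-08; 7 adjusted over the list alone), mitochondrially encoded mRNAs (adjusted p = 7.24e-06; 5), fibroblast markers (adjusted p = 1.47e-05; 3), complement (adjusted p = 0.00108; 6), adipocyte markers (adjusted p = 0.00366; 5), cholesterol synthesis (adjusted p = 0.00366; 2) and fatty acid oxidation (adjusted p = 0.005; 3) went up, each with an adjusted p of 0.552 estimated. Smooth muscle and pericyte markers (adjusted p = 0.0267; 4; adjusted p = 0.552 estimated) and MHC class I presentation (adjusted p = 0.0267; 0; adjusted p = 0.562 estimated) went up as well. Fast fibre genes (adjusted p = 0.00366; 2 up and 4 down adjusted over the list alone), glycolysis and glycogen (adjusted p = 0.005; 1 up and 3 down) and denervation response (adjusted p = 0.0406; 0) went down, each with an adjusted p of 0.552 estimated. Muscle atrophy genes (adjusted p = 0.0156; 1 down adjusted over the list alone) and cell cycle genes (adjusted p = 0.0307; 0) went down, with an adjusted p of 0.562 estimated. Without libraries 3.1 and 2.2, the denervation response lost its call (adjusted p = 0.068).

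The gastrocnemius exercise count moved with many libraries. It was 686 without libraries 3.1 and 2.2, which include the 16 original calls, and 336 without 3.1 alone. It was 133 without 5.4, 94 without Gas_10.1, 88 without 2.2, 70 without Gas_10.3, 56 without 6.1, 36 without 5.1 and 32 without 8.3. It was 3 without 6.2, 5 without 4.3 or without 7.4, 7 without 8.2, 8 without 6.4, 9 without 7.3 and 10 without 7.1 or without 9.2. Libraries 3.1 and 2.2 belong to neither group compared and enter through the shared estimate of the spread. Myh1, Hmgb3 and Fzd7 stayed called in every such fit.

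In quadriceps at 18 months, Fhl1, a muscle LIM protein gene, myoglobin, the fast myosins Myh1 and Myh2 and the calcium pump regulator Sln rose with exercise. Of 14790 genes, 88 were higher and 24 lower, with 1692 at an unadjusted p under 0.05 where chance gives 740. With 2 surrogate variables 349 were higher and 306 lower.

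Quadriceps Fhl1 rose from 671 ± 102 (n = 9) to 1390 ± 356 CPM (SD, n = 12), by 1.05 ± 0.169 (SE, edgeR adjusted p = 0.000958), above the sedentary median in 12 of 12 libraries. Mb rose from 1929 ± 252 to 3601 ± 860 CPM, by 0.90 ± 0.143 (adjusted p = 0.000958). Myh1 rose from 5077 ± 505 to 9110 ± 2606 CPM, by 0.84 ± 0.141 (adjusted p = 0.00122), and Myh2 from 2063 ± 150 to 3666 ± 743 CPM, by 0.83 ± 0.168 (adjusted p = 0.00969), with all 12 exercised libraries above every sedentary one for Myh2. Sln rose by 0.995, Acly by 0.94, the cartilage matrix gene Cilp by 0.87, the sarcomere gene Myom3 by 0.86 (adjusted p = 0.00182), Trp53i11 by 0.85 and Ttc9 by 0.82. Ocrl, an inositol phosphatase gene, had a log2 fold change of -0.32 ± 0.0525 (adjusted p = 0.000958), below every sedentary library in 12 of 12. The interferon-induced gene Gbp10, which shares 1792 exon bases with Gm43302 and is uncertain, fell by 0.72, Fam57b by 0.56, the gluconeogenic enzyme gene Fbp2 by 0.55, Nt5e by 0.49, the iron exporter gene Slc40a1 by 0.43 and Asb4 by 0.41. Sorbs2 fell by 0.39, Epb41l4b by 0.39 and Nktr by 0.33; Sorbs2 and Nktr share 1051 and 2182 exon bases with opposite-strand genes. Of list members, the cholesterol synthesis gene Acat2 rose by 0.49 and the small heat shock gene Cryab by 0.41. Myh4 (-0.21, adjusted p = 0.437), Myh7 (0.19, adjusted p = 0.722) and Ppargc1a (0.04, adjusted p = 0.849) did not pass, nor did Chrna1, Myog, Col1a1, Col3a1 or Cdkn1a (adjusted p = 0.167, 0.727, 0.814, 0.998 and 0.801).

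Of the quadriceps lists, 11 were called with exercise, again with every call lost under an estimated correlation. Nuclear oxidative phosphorylation was fitted up in 52 of 52 genes with 0 called over all genes and 19 adjusted over the list alone (adjusted p = 3.46e-19), and slow fibre genes in 14 of 14 with 5 adjusted over the list alone (adjusted p = 3.68e-06; adjusted p = 0.687 estimated for both). Endothelial markers (adjusted p = 0.000421; 5 adjusted over the list alone), mitochondrially encoded mRNAs (adjusted p = 0.00141; 0), smooth muscle and pericyte markers (adjusted p = 0.00465; 4 up and 1 down), cholesterol synthesis (adjusted p = 0.00795; 1), denervation response (adjusted p = 0.0252; 6 up and 1 down) and B and plasma cell markers (adjusted p = 0.0416; 0) went up, each with an adjusted p of 0.687 estimated. Interferon response (adjusted p = 0.0124; adjusted p = 0.803 estimated) and fatty acid oxidation (adjusted p = 0.0416; adjusted p = 0.836 estimated) went up and ER stress went down (adjusted p = 0.0265; adjusted p = 0.687 estimated), with 0 members adjusted over the list alone. No list passed in fry, where the smallest adjusted p was 0.348. Without library 3.1, B and plasma cell markers lost their call (adjusted p = 0.0643). Of the muscle lists not called in any comparison, satellite cell markers had adjusted p-values of 0.129 and 0.135 with age, circadian clock genes 0.0923 and 0.733, and endurance training targets 0.172 and 0.682, in gastrocnemius and quadriceps. For p53 targets and senescence these were 0.737 and 0.96, for glucocorticoid response 0.75 and 0.948, for macrophage and microglia markers 0.809 and 0.135, and for immediate early genes 0.75 and 0.41.

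The quadriceps exercise count was 341 without library 3.1, which belongs to neither group compared, 218 without 5.4 and 197 without 9.1. It was 60 without 4.3, 63 without 6.2, 68 without 7.3, 70 without 7.1 and 73 without 7.4. Fhl1, Sln, Mb, Myom3, Myh1, Myh2, Ttc9, Slc40a1, Sorbs2 and Ocrl stayed called in every such fit.

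Both muscles shared 5 exercise calls of the same direction, Acly, Mb and Myh1 up and Mylk2 and Wbp1l down. Fold changes correlated across genes with r = 0.51. As for ageing, libraries of both muscles with the same number are not independent, and their part in this agreement was not tested. No gene passed for a difference in the exercise effect between the muscles: edgeR and DESeq2 each called 0 of 15433, with 357 at an unadjusted p under 0.05 where chance gives 772. Here too the count lies below chance, so it is not evidence that both muscles respond alike. The 5 smallest p-values belonged to Aif1l, Nlrp10, Ibsp, Fgf14 and Myh8 (adjusted p = 1 each).

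In spinal cord no gene passed for exercise. The microglial and astrocyte genes that were higher with age were at similar levels in exercised and sedentary mice. edgeR called 0 of 18956 genes (smallest adjusted p = 0.368), with 2565 at an unadjusted p under 0.05 where chance gives 948. DESeq2, limma with quality weights and limma on TPM called 0 as well, as did every fit that left out 1 library. Without cord libraries 5.2 and 6.1, 764 genes had an unadjusted p under 0.05 (smallest adjusted p = 1). On simulated counts without trends of single libraries, the same fit recovered 80.6% of 1.3-fold changes in genes above the lowest expression.

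The 5 smallest p-values in exercised cord belonged to the amino acid oxidase gene Dao (log2 fold change -0.40), the plakophilin gene Pkp3 (-0.82), the G protein regulator gene Rgs7 (0.12), the serine dehydratase gene Sds (-0.26) and Cog8 (-0.15), which shares 1306 exon bases with Pdf, each with an adjusted p of 0.368. Cst7 lay at 2.09 ± 0.429 CPM in exercised (n = 13) and 2.41 ± 0.475 in sedentary 18-month mice (SD, n = 10; -0.21, adjusted p = 0.478). Gfap (-0.07, adjusted p = 0.509), C4b (-0.15, adjusted p = 0.371), C1qa (-0.22, adjusted p = 0.368), Mbp (-0.11, adjusted p = 0.368), Chat (0.02, adjusted p = 0.895) and Snap25 (0.08, adjusted p = 0.419) did not pass.

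In cord 13 lists were called with exercise, and each call was lost with an estimated correlation (adjusted p = 0.619 for all 13) and in fry (smallest adjusted p = 0.284). Mitochondrially encoded mRNAs (adjusted p = 1.89e-06; 3 members adjusted over the list alone) and cholesterol synthesis (adjusted p = 0.00042; 2) went up. Sedentary library 5.2 had 1.58% mitochondrial counts and the other 9 sedentary 18-month libraries between 3.99% and 4.63%; without 5.2 and 6.1 the list of mitochondrially encoded mRNAs stayed up (mitochondrially encoded mRNAs: adjusted p = 5.01e-08), while oxidative phosphorylation lost its call (oxidative phosphorylation, nuclear: adjusted p = 0.776). MHC class I presentation (adjusted p = 0.000178), immediate early genes (adjusted p = 0.000385), ER stress (adjusted p = 0.00042; 2 adjusted over the list alone), nuclear oxidative phosphorylation (adjusted p = 0.000732), interferon response (adjusted p = 0.0124), collagens and matrix (adjusted p = 0.0181), endothelial markers (adjusted p = 0.0181) and complement (adjusted p = 0.0199) went down. So did B and plasma cell markers (adjusted p = 0.0292), neutrophil and marrow markers (adjusted p = 0.0434) and MHC class II presentation (adjusted p = 0.0459). Red cell markers had a median of -1.29 with 8 of 8 fitted down and 8 down adjusted over the list alone, and were not called (adjusted p = 0.0858). Apart from sedentary library 6.1 at 11106 CPM, the exercised libraries, at 267.9 to 1878 CPM, overlapped the sedentary ones, at 199.6 to 1029 CPM. Disease-associated microglia genes were not called (median -0.05, adjusted p = 0.0684).

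Cord and muscle differed in their exercise effect for some genes, among them Elovl6 and Slc25a1, which rose in gastrocnemius, and Rec8, which rose in quadriceps. Of 19735 genes, 56 had a higher and 119 a lower effect in cord than in the muscles, with 3161 at an unadjusted p under 0.05. The difference was -2.14 ± 0.337 (SE, log2) for the meiotic cohesin gene Rec8 (adjusted p = 0.000139), -1.23 for Elovl6, -1.17 for Slc25a1 (adjusted p = 0.00292), -1.16 for the postsynaptic scaffold gene Dlgap3 and -1.104 for Tmem179. It was 0.51 for Cpeb4, a translation regulator gene, 0.51 for Ttll7, 0.49 for Epb41l4b (adjusted p = 0.0051), 0.49 for Tmem132b and 0.49 for the lipoprotein receptor gene Vldlr. Without the libraries that stood apart, 108 genes were called.

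**Figure D4:**
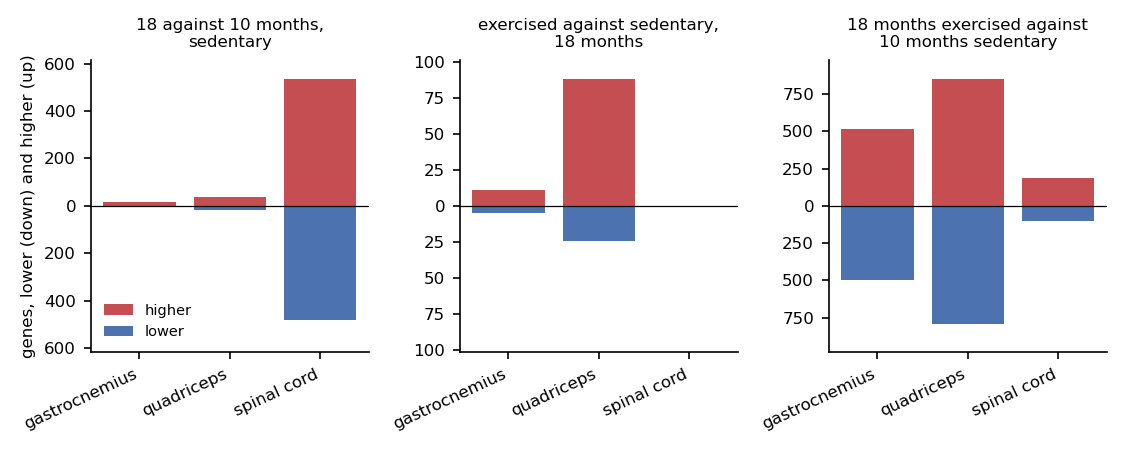
Numbers of genes called higher (red, upward) and lower (blue, downward) at an adjusted p under 0.05 in each tissue, for the 3 comparisons, with a separate count axis in each panel. Cord has the most calls with age, 1015, and 0 with exercise, while both muscles have the most for exercised 18-month against sedentary 10-month mice.

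Exercised 18-month mice were also compared with sedentary 10-month mice, a difference of both age and exercise. Gastrocnemius had 515 genes higher and 496 lower, with 3663 at an unadjusted p under 0.05. Quadriceps had 852 higher and 795 lower, with 4197, and cord 186 higher and 100 lower, with 2582. The genes named here for this comparison were chosen after their values were seen. In gastrocnemius Lep had a log2 fold change of -2.42 ± 0.376 (SE, adjusted p = 0.000299), and in quadriceps one of -1.72 ± 0.264 (adjusted p = 7.94e-05). Quadriceps Sh2d4a rose by 1.003 ± 0.102 (adjusted p = 2.40e-07), Sln by 1.86 and Fasn, the fatty acid synthase gene, by 1.72. In cord Gpnmb rose by 1.953 ± 0.194 (adjusted p = 3.58e-08) and Lgals3 by 1.54, and Gpr17 had -0.73. Without the libraries that stood apart, the counts were 1004 in gastrocnemius (613 shared with the original calls), 1601 in quadriceps and 689 in cord (286 shared).

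In cord, most genes that changed with age had the opposite fitted sign under exercise. This was so for 950 of 1015 genes (93.6%), against 15 of 23 (65.2%) in gastrocnemius and 28 of 52 (53.8%) in quadriceps. Both comparisons use the same 18-month sedentary libraries, and simulated unchanged groups gave 91.5%, 98.3% and 96.3% in cord, gastrocnemius and quadriceps. These simulated shares are over the genes with the smallest ageing p, as many as were called in the real data. None of these genes carries an age effect, so the shares are no baseline for genes that truly changed with age. The covariance of both fold changes across genes was -0.0158 in cord and -0.00796 in simulated groups, a difference of -0.00788. In gastrocnemius it was -0.0076 and -0.00972 simulated, a difference of 0.00213, and in quadriceps -0.00399 and -0.0112, a difference of 0.00722. The sedentary libraries were also split between the comparisons, in 10 splits. The median share was then 77.2% in cord (41.3% to 88.3%), 27.4% in gastrocnemius (0% to 100%) and 19.4% in quadriceps (7.1% to 66.7%). These shares are over the genes called in each split, a median of 381, 3.5 and 17. Over the original ageing calls the splits gave 70.5% to 92.8% in cord, 56.5% to 73.9% in gastrocnemius and 36.5% to 55.8% in quadriceps. Those calls were chosen with all sedentary libraries, which favours opposite signs.

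At 10 months, many genes differed between gastrocnemius and quadriceps. The limb patterning genes Hoxd10 and Hoxd9 were higher in gastrocnemius and the developmental regulator Tbx1 was higher in quadriceps. Of 15433 genes, 1043 were higher and 644 lower in gastrocnemius, with 3740 at an unadjusted p under 0.05. Hoxd10 differed by 2.91 ± 0.302 (SE, log2; adjusted p = 6.82e-11), Hoxd9 by 2.27, the metallothionein gene Mt3 by 2.34 and the secreted phosphoprotein gene Spp1 by 2.25; Zbed6, at 2.29, shares 5007 exon bases with Gm38394 on the same strand and is uncertain. Tbx1 differed by -3.02 ± 0.268 (adjusted p = 5.19e-13), Cyp4f39 by -2.94, Lrtm2 by -2.62, Katnal2 by -2.55 and the lubricin gene Prg4 by -2.35. Without the libraries that stood apart, 3886 genes were called.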

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

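Of the tests in this part, those of gene length and of a wrong label for library 3.1, and those of the opposite signs in cord, were chosen after the result was seen. The group tests of correlations with gene length and GC content were chosen after the data were seen. Values of a single library stand here because that library lay far from the others of its group by Dixon's test, which chance meets in about 1 in 20 groups. It was met in 16 of 48 groups of library measures and 44 of 230 groups of gene values. Only groups of up to 10 libraries were screened, so no exercised group, with 12 or 13, was covered. The comparisons of cord with muscle stand here because the effects differed by a test of the difference.

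In both muscles, library 3.1 (10 months, sedentary) lay apart, with the 10 most abundant genes at 21.8% of counts in gastrocnemius and 22.5% in quadriceps and a root mean square deviation of 0.753 in quadriceps. Gene length (larger correlation 0.019) and GC content (-0.066) do not account for it. Nor does added RNA of the cell types covered by 9 marker lists, since the highest median in both libraries was -0.184. That test sees only an excess, so a loss of a cell type stays open. A single wrong label is excluded by the correlation of 0.903 between the differences of both libraries, but a wrong label for both stays open. Its muscle atrophy genes were higher by 1.35 and 1.68 and its collagens lower, at -1.56 and -1.43, in gastrocnemius and quadriceps. No biological explanation was tested, as the labels set this library in no group of its own.

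Gastrocnemius library 3.1 had Col11a2 at 1.83, Col1a1 at 18.8, Col3a1 at 43.8, Myh2 at 847, Myh4 at 41162 and Myog at 11.4 CPM, Myog being the highest and the others the lowest of 10. Quadriceps library 3.1 was lowest of 10 for Cilp (24.9 CPM), Col1a1 (12.2), Col3a1 (18.6), Epb41l4b (9.23), Fam57b (15.8), Fhl1 (223), Mb (871), Myh2 (464), Myh4 (39745), Myom3 (16.3), Sorbs2 (61.7) and Trp53i11 (3.35). It was highest for Cdkn1a (75.7 CPM), Cry1 (27.3), Dnajb4 (130) and Myog (10.7). Cord library 3.1 was highest of 10 for C1qa (89.0 CPM), C4b (210), Gfap (1429) and Lilrb4a (4.27).

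Cord libraries 5.2 and 6.1 (18 months, sedentary) have trends with GC content or gene length, which could account for the cord ageing calls. Over all sedentary cord libraries, the mean correlation with GC content was 0.102 ± 0.244 at 18 and -0.095 ± 0.112 at 10 months (SD, permutation p = 0.0182, adjusted p = 0.182). That with gene length was -0.078 ± 0.229 and 0.096 ± 0.142 (permutation p = 0.0548, adjusted p = 0.274). Leaving out these 2 libraries does not test a trend shared by other libraries. Library 5.2 had the highest GC correlation, 0.684, and the lowest mitochondrial share, 1.58%, and share of the 10 most abundant genes, 5.61%, while 6.1 had red cell transcripts at 11106 CPM. Without both, the disease-associated microglia list kept 86.5% of its median log2 fold change, so these libraries do not account for its rise. The called rises kept 89.4% of their median, at 0.31 in place of 0.35, with 535 of 535 signs kept and 274 still called. The falls kept 70.6% of theirs, at -0.13 in place of -0.18, with 480 of 480 signs kept. Most libraries are the same in both fits, which makes a kept sign likely. Of the falls, 119 of 480 stayed called, so whether these libraries made part of the falls is undecided. The called falls had a median length of 4566 bases and GC content of 44.9%, against 3339 bases and 49.8% over all tested genes. The called rises were shifted the other way, at 2302 bases and 53.7%, and the disease-associated microglia list lay at 1806 bases and 51.2%. A part of length or GC content in the rises is therefore not excluded either.

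In cord, 93.6% of the genes changed with age had the opposite sign under exercise. The 18-month sedentary libraries enter both comparisons, which alone could give opposite signs. With these libraries split between the comparisons the median share was 77.2%, and without 5.2 and 6.1 it was 63.9% (19.1% to 84.9%). The median covariance of both fold changes over the splits was -0.00518 with these 2 libraries and 0.000233 without, and the cause stays undecided. A biological explanation, that exercise partly reverses ageing in cord, is not separated from these, as no gene passed for exercise.

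Other splits of the samples into groups of the same sizes show how often shuffled libraries gave as many calls. They treat libraries as exchangeable, so they cannot exclude a structure of the samples, such as litters or cages. Beside each count stand the splits of 100 that gave as many, the real one included, and the highest other count. For ageing only the real grouping reached its count in gastrocnemius (23, 1 and 1), quadriceps (52, 1 and 2) and cord (1015, 1 and 0). The same held for exercise in gastrocnemius (16, 1 and 1). For exercised 18-month against sedentary 10-month mice it held in gastrocnemius (1011, 1 and 776) and cord (286, 1 and 0). Shuffling alone does not account for these counts. In quadriceps 1 other split gave more calls than the real grouping, for exercise (112, 2 and 930) and for the last comparison (1647, 2 and 1702). No exclusion of chance is drawn there. What set the split with 930 calls apart from the others was not tested. For exercise in cord 0 genes were called, so that 100 of 100 splits must give as many and say nothing about chance. The highest other count was 5699. All 5 splits with calls put cord libraries 5.2 and 6.1 on the same side. So did many splits with 0 calls, the real grouping among them, and 1 of the 5 had only 1 call.

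For the number of gene lists called, chance cannot be excluded in any comparison by these splits: ageing in gastrocnemius (11 called; 57 of 100 splits gave as many; highest other 21), quadriceps (8; 93; 21) and cord (12; 36; 22), and exercise in gastrocnemius (16; 6; 19), quadriceps (11; 35; 19) and cord (13; 24; 22). These counts say nothing about a given list, and disease-associated microglia genes in cord ageing passed with an estimated correlation (adjusted p = 0.000766) and in fry (adjusted p = 1.11e-09). For the share of opposite signs it cannot be excluded either, in gastrocnemius (65.2%; 86 of 100 splits; highest other 97.2%), quadriceps (53.8%; 95; 95.7%) and cord (93.6%; 7; 96.0%). Between cord and muscle only the real grouping reached its count, for ageing (516, 1 of 40 splits, highest other 1) and exercise (175, 1 and 4). For the muscles' difference in ageing (0; 60 of 60; 0) and exercise (0; 60 of 60; 0) the count of 0 makes the splits say nothing. At 10 months (1687; 5 of 60; 2437) these splits, which treat the libraries of both muscles as unrelated, do not exclude chance for the count. The 4 larger ones put both 3.1 libraries in 1 group, and without the libraries that stood apart 3886 genes were called. For Tbx1 and Hoxd10 chance is excluded by their own tests (adjusted p = 5.19e-13 and 6.82e-11).

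Cord and muscle differed in the ageing effect of 516 genes, with differences of 2.04 for Rnf182, 1.77 for Gpnmb, 1.75 for Dscaml1, 1.65 for Nnat, 1.57 for Mt1, -1.59 for Slc15a2, -1.35 for Fam174b, -1.35 for Stxbp5l, -1.14 for Arc and -1.09 for Rspo2. They differed in the exercise effect of 175 genes, with 0.51 for Cpeb4, 0.51 for Ttll7, 0.49 for Epb41l4b, 0.49 for Tmem132b, 0.49 for Vldlr, -2.14 for Rec8, -1.23 for Elovl6, -1.17 for Slc25a1, -1.16 for Dlgap3 and -1.10 for Tmem179.

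Gastrocnemius library 2.2 was lowest of 10 in genes detected (19299), mitochondrial share (7.15%), correlation with gene length (-0.487), Ppargc1a (27.6 CPM) and Sh2d4a (2.33 CPM). Quadriceps library 5.2 was highest of 9 in mitochondrial share (19.2%) and in the share of the 10 most abundant genes (33.5%), and quadriceps library 3.2 highest of 10 in mitochondrial share (18.2%). Library 6.1 had the highest red cell transcripts in gastrocnemius (1284 CPM) and quadriceps (1107 CPM) at 18 months, and library 2.3 in quadriceps at 10 months (530 CPM). Gastrocnemius library 9.3 was highest for Acly (29.7 CPM), Elovl6 (3.08) and Slc25a1 (10.38), 6.4 for Hmgb3 (4.64) and 3.2 for Fam174b (4.61), and 6.1 was lowest for Tmem132b (8.79). Quadriceps library 9.3 was lowest for Mb (1363 CPM) and highest for Nt5e (3.82), 7.4 lowest for Fam57b (21.1), 4.3 highest for Myog (3.66) and 1.4 highest for Jchain (3.71). Cord library 5.2 was lowest for Clec7a (2.25 CPM), Lilrb4a (2.49) and Snap25 (1880), 9.3 highest for LOC101056014 (1319) and 6.1 highest for Rsad2 (39.96).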

How the results depend on the processing

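No test of an explanation was made in this part, but 2 settings, leaving out the libraries that stood apart and a covariate for the slope on gene length, were chosen after seeing the data. Named genes kept their sign in 2340 of 2341 values under other settings within tissues and in 234 of 235 between tissues. Of the values within tissues, 191 come from the fold change minimum, which leaves every sign as it was. Many of these genes were named for large changes in the same data, which makes a kept sign likely. For lists, an estimated correlation cannot turn a direction either. The 71 called lists kept their direction under each setting for lists, but 1 kept its call with an estimated correlation, 11 in fry, 59 without the libraries that stood apart, and 60 of 68 with a mean count of at least 50. For each value below the cause was not tested, except that a fold change limit by construction removes calls. Small changes can be missed: on simulated counts 44.8% of 1.3-fold changes were recovered for ageing in quadriceps and 80.6% for exercise in cord.

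Counts of genes are given for ageing, then exercise, then exercised 18-month against sedentary 10-month mice. DESeq2 called 75 and 201 in gastrocnemius, 120 and 222 in quadriceps, 1612 with age in cord and 499 in the last comparison there, and 1019 (ageing) and 482 (exercise) between cord and muscle. limma with quality weights called 481, 1067 and 1865 in gastrocnemius, 833, 634 and 2531 in quadriceps, and 2260 with age and 2654 in the last comparison in cord; Cdkn1a in quadriceps ageing turned its sign to 0.49. With 2 surrogate variables the counts were 225, 824 and 1845 in gastrocnemius, 253, 655 and 2856 in quadriceps, and 1 (Dao, -0.28, adjusted p = 0.0429, named after its value was seen) for exercise and 1402 for the last comparison in cord. With RLE factors exercise in gastrocnemius called 25. With only both compared groups fitted, gastrocnemius called 184 for exercise and 371 for the last comparison, quadriceps 17 for ageing and 1085 for the last, and cord 252 and 644.

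limma on log2(TPM + 1) called 11 with age and 558 in the last comparison in gastrocnemius, and 8, 36 and, rounded, 6.0e+02 in quadriceps; with 0.1 added these were 6 and 550, and 11, 25 and 551. Without a low-count filter gastrocnemius called 10 for exercise and, rounded, 6.0e+02 for the last comparison, cord 540 for ageing, and cord against muscle 284 for ageing and 90 for exercise. With a mean count of at least 50, gastrocnemius ageing called 11. An absolute log2 fold change of at least 0.5 left 15, 9 and 282 in gastrocnemius, 62 for exercise and 535 for the last comparison in quadriceps, and 163 for ageing and 90 for the last in cord. The slope on gene length gave 36, 219 and 1822 in gastrocnemius, 31 for ageing and 66 for exercise in quadriceps, and 1272 for the last comparison in cord. With the first part of the number as a block, gastrocnemius called 1360 for exercise (801 up and 559 down) and quadriceps 94 (54 up and 40 down), of which 44 were among the original 112.

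Without the libraries that stood apart, gastrocnemius called 49 for ageing and 686 for exercise, quadriceps 113 and 341, and cord 454 for ageing and 689 for the last comparison, with 20 lists for exercise in cord. Cord against muscle then called 252 for ageing, where Mt1 turned its sign to -0.09, and 108 for exercise, and the muscles at 10 months 3886. Leaving out 1 library at a time, ageing counts ran from 3 to 80 in gastrocnemius, 18 to 113 in quadriceps and 407 to 1892 in cord, and exercise counts from 3 to 336 in gastrocnemius, 60 to 341 in quadriceps and 0 to 0 in cord.

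Lists called with an estimated correlation numbered 0 for ageing and 0 for exercise in gastrocnemius, 0 and 0 in quadriceps and 1 and 0 in cord, and in fry 1 and 1 in gastrocnemius, 0 and 0 in quadriceps and 0 for exercise in cord. With the sedentary libraries split, medians of 3.5, 17 and 381 genes were called in gastrocnemius, quadriceps and cord. The share of opposite signs was then 27.4%, 19.4% and 77.2%. Without the libraries that stood apart, and with no split, it was 87.7% in cord. With a mean count of at least 50, both muscles shared 6 ageing calls and 9 exercise calls, and quadriceps and cord shared 1 ageing call; with RLE factors the muscles shared 10 exercise calls.

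With the number in the title as a replicate block, cord against muscle called 1490 for ageing and 867 for exercise, and the muscles at 10 months 3711, while the muscles' difference stayed at 0 for ageing and 0 for exercise. The samples share only this number. As a hint from the data, 23 of 31 quadriceps libraries correlated best with the gastrocnemius library of their own number, with a median r of 0.28 for the same (over 0.1 in 28 of 31) and -0.002 for other numbers, against 5 of 33 between gastrocnemius and cord and 3 of 31 between quadriceps and cord.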
